A study of Mus musculus with 4 samples.

How the data were processed

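Polyadenylated RNA of mouse embryonic stem cells was measured by RNA sequencing in 4 samples, 2 wild type and 2 lacking both Gsk3a and Gsk3b. Per the labels' protocols, cells were kept in serum medium with leukaemia inhibitory factor on irradiated mouse embryonic fibroblasts, RNA was extracted with TRIzol, and stranded TruSeq libraries were made. The sample labels give an embryonic day of 16. The design text gives another value, which may be an age or the name of a cell line. STAR, DESeq and the genome build mm10 are named in the submitters' processing notes without versions. The read counter, its strand setting, the annotation release and any filter are not given in the sources used here.

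The data are 1 table of a comparison between a group A and a group B, as the file's header names them. Neither the header nor a label says which genotype is A and which is B, so results are stated for group B over group A and no genotype is assigned in the report. The authors' deposited table gives, per gene, the mean normalized count of each group, their ratio (fold change), its log2, a p-value and an adjusted p-value. A normalized count is a gene's read count divided by the library's size factor. The table has 46608 rows for 46603 gene IDs, and the 5 repeated rows were used once. A count was present for 30237 genes. The authors' adjusted p-value differed from a Benjamini-Hochberg adjustment over these 30237 genes by at most 3.66e-15. Chromosome positions were taken from GENCODE M21 on the same build, which matched 46091 gene IDs and left 512 without a position.

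The authors' test was used as deposited, with an adjusted p of 0.05 as the threshold, because the table holds no value of a single sample. The design written before the data were examined foresaw this case. The mean of a group over 2 libraries is a sum of whole reads of 1 library times a first step and whole reads of the other times a second step. These steps are the smallest values of the group's column, and they gave whole counts within a tolerance of 1e-06 for all 28616 genes with a mean in group A and all 28353 in group B. The largest distance from whole numbers was 6.98e-09 in group A and 2.21e-09 in group B. A second pair of counts also lay within the tolerance for 1700 genes of group A and 11 of group B, so the closest pair was taken, and in every gene the next best pair lay at least 20.5 times farther from whole numbers. The steps equalled the median-of-ratios size factors of the recovered counts within 1.55e-15. The recovered libraries are called A1, A2, B1 and B2, and these numbers are not the replicate numbers of the labels. Total counts were 143182371 in A1, 134463318 in A2, 146326307 in B1 and 112655210 in B2. At this depth counting error is small for abundant genes, and the spread between the 2 libraries of a group limits the precision.

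Recovering the counts was decided after seeing the table, so tests on them are alternatives. They used limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(normalized count + 1) of the 20465 genes with a mean of at least 10, two-sided, with Benjamini-Hochberg adjustment. Fold changes on this scale understate the change of genes with low counts. Count-based tests were left out, and the recovered counts were tested with limma alone.

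The 30 gene lists, with 674 entries, were fixed before the data were examined. For each list with at least 5 members at a mean of at least 10, the number of members past the threshold was counted over all genes and adjusted over the list alone. The median log2 fold change was set against 10000 random lists of the same size, drawn from 20 bins of mean expression, with Benjamini-Hochberg adjustment over the 29 lists that could be tested. This two-sided random-list p describes the table and is not a test across samples. The limma function camera was run on the recovered counts with a preset correlation of 0.01 and with an estimated one. The estimated setting rests on the spread within groups of 2 libraries, and its power was not measured. A list that misses it is not shown to be unchanged.

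Genes were named by a rule fixed in advance. It took Gsk3a and Gsk3b, then the 12 largest increases and 12 largest decreases among genes past the threshold with a mean of at least 50, a symbol that is not a predicted-gene or pseudogene name, and both libraries of a group on the same side of both others. From each list it took up to 4 members past the threshold with the smallest adjusted p, or the 2 members with the highest mean. Genes named outside this rule are marked as chosen after their values were seen.

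The procedures were tested on simulated counts for the real genes and library sizes, with 200 changed genes and a dispersion of 0.0375. Both counts came back for 100% of the 28508 genes with a mean in group A and of the 28419 in group B. In the comparison of 2 against 2 simulated libraries over 20437 genes, limma called 4.48% of the genes changed 1.5-fold, 38.8% of those changed 2-fold and 100% of those changed 4-fold, and it called 9 unchanged genes. Of 200 simulated lists of 25 unchanged genes, 3% had a random-list p under 0.05, against 100% of lists shifted by 1 on the log2 scale. The simulated genes varied independently, so the 3% does not hold for lists whose members vary together. Camera estimated a correlation of 0.98 for the feeder fibroblast list and 0.89 for the 2-cell-like list. It was 0.60 for glycolysis and hypoxia, 0.54 for endoderm, 0.48 for general pluripotency, 0.42 for sterol and fatty acid synthesis and 0.36 for lysosome. The random-list p values of these lists are therefore too small to an unknown degree. Estimates were -0.03 for Wnt targets, -0.05 for trophectoderm, 0.06 for naive pluripotency and 0.11 for cell cycle. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and BLAST 2.17.0 compared transcripts.

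Alternatives covered the threshold, a minimum fold change, filters on low means, the adjustment, pseudocounts, scaling, the summary and matching of lists, the set test and the libraries left out. Splicing was not analysed here, since the table holds 1 value per gene.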

Results

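The transcriptome of mouse embryonic stem cells without glycogen synthase kinase 3 was compared with that of wild-type cells, with 2 biological replicates of each genotype. Gsk3a and Gsk3b encode the 2 forms of this kinase, which among other roles marks beta-catenin for degradation and so holds Wnt signalling down. Values are given for group B over group A, because the sources used here do not say which genotype is which group. Library totals recovered from the group means ranged from 112655210 to 146326307 counts, and 26436 to 26994 genes had a count in each library. Across 16553 genes with a mean of at least 50, Pearson's r of log2 normalized counts was 0.993 between A1 and A2, 0.983 between B1 and B2, and 0.972 to 0.976 between groups. Genes are not independent replicates, so these values only describe the libraries.

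Of the genes that the study targeted, Gsk3a (ENSMUSG00000057177, chromosome 7, 25228258 to 25237851, mm10) was lower in group B. Recovered normalized counts of Gsk3a were 6353 in A1, 7104 in A2, 1697 in B1 and 1347 in B2. The authors' deposited table gives it a log2 fold change of -2.14 with an adjusted p of 4.90e-24. For Gsk3b (ENSMUSG00000022812, chromosome 16, 38089001 to 38246084) the recovered values were 5438, 6285, 5051 and 5002, and the log2 fold change in the authors' deposited table was -0.22 with an adjusted p of 0.984. With limma on the recovered counts the log2 fold change was -2.15 (SE 0.16, adjusted p = 0.0255) for Gsk3a and -0.22 (SE 0.12, adjusted p = 0.365) for Gsk3b. Without A1 the limma adjusted p of Gsk3a was 0.139 and without A2 0.308, with log2 fold changes of -2.23 and -2.07. The labels do not describe the alleles, and a gene can keep a transcript that is counted after part of it is deleted.

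The comparison between the groups asked which transcripts differ when both kinase genes are lost. Past the threshold in the authors' deposited table, 8 of 26 canonical Wnt target genes and 11 of 25 lysosomal genes were higher in group B, and 3 of 11 general pluripotency factors and 3 of 15 genes of the 2-cell-like state were lower. By the authors' deposited table, 1047 of 30237 genes passed an adjusted p of 0.05, 466 higher and 581 lower in group B. Among them 262 had a log2 fold change above 1 and 340 below -1, and the median absolute log2 fold change was 1.11. All 1047 had both B libraries on the same side of both A libraries. A call nearly requires this, so it adds no support for the calls. Over all genes with a mean of at least 10 the share was 52.5%, against 33.3% by chance. With limma on the recovered counts 411 genes passed, 389 of them also past the authors' threshold and all of these in the same direction. Leaving out 1 library in limma puts the spread on the other group's pair alone. In genes with a mean of at least 50, the standard deviation of the log2 ratio was 0.519 between B1 and B2. Between A1 and A2 it was 0.340. The number of genes called without 1 library therefore depends on the pair left, and it does not show which library the calls rest on.

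Canonical Wnt target genes included the largest increase of a named gene, that of T. Of 26 measured members, 8 were higher and 0 lower in group B over all genes, and 12 were higher and 0 lower adjusted over the list alone, with a median log2 fold change of 0.57 in the authors' deposited table. T (ENSMUSG00000062327, chromosome 17, 8434423 to 8442496), the mesoderm transcription factor brachyury, went from a mean of 307 in group A to 5314 in group B (log2 fold change 4.11, adjusted p 3.51e-38, authors' deposited table). Sp5 (ENSMUSG00000075304, chromosome 2, 70474923 to 70477729), a transcription factor induced by beta-catenin, rose by 3.50 on the log2 scale (adjusted p 1.07e-41), Axin2, a feedback inhibitor of the pathway, by 2.21 (2.34e-27) and Rnf43, which removes Wnt receptors from the cell surface, by 2.00 (2.39e-07), as the authors' deposited table gives them. Each of the 4 genes also passed in limma (T 4.10, SE 0.16, adjusted p = 0.00782; Rnf43 2.01, SE 0.30, adjusted p = 0.0416). The random-list adjusted p of the list was 0.00116, from an unadjusted p of 0.0002 that is the smallest 10000 lists can give, and the adjusted p = 0.57 with an estimated correlation. Limma called 7 members higher and 0 lower with all libraries. Its median log2 fold change of the list was 0.55 without A1, 0.60 without A2, 0.55 without B1 and 0.59 without B2. Wnt pathway components, the machinery itself, had 1 of 25 members past the threshold over all genes and also adjusted over the list alone. It was Wnt7b, a Wnt ligand, which fell by 1.05 on the log2 scale (adjusted p 0.00681, authors' deposited table).

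**Figure D1:**
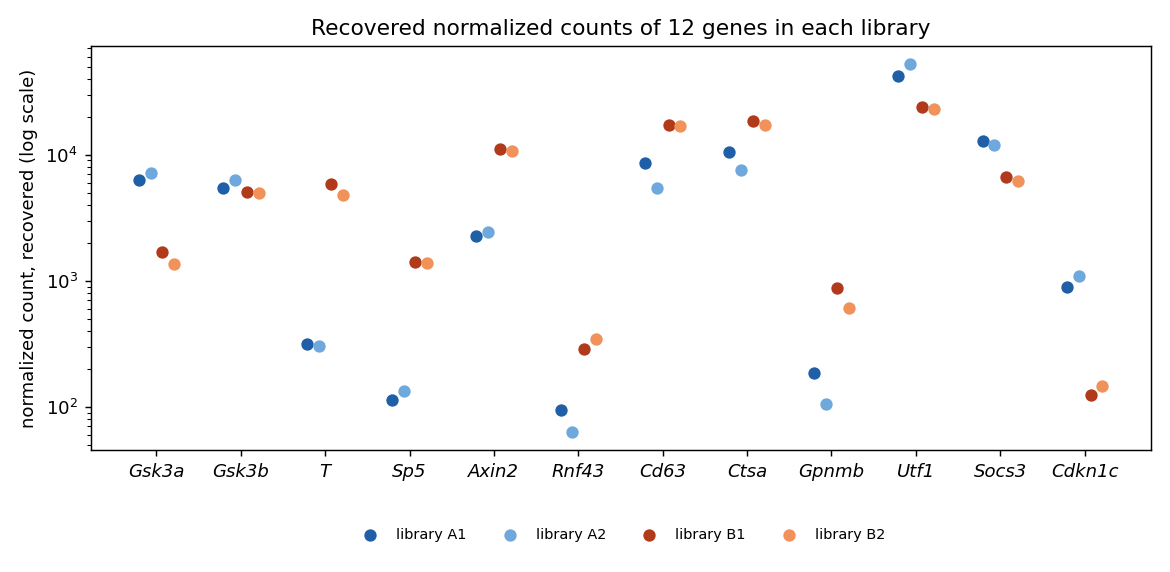
Recovered normalized counts (vertical log axis) of 12 genes in libraries A1 and A2 (blue) and B1 and B2 (orange), 1 point per library and no error bars. Both B libraries lie below both A libraries for Gsk3a, Utf1, Socs3 and Cdkn1c and above them for the Wnt target and lysosomal genes shown, and the Gsk3b values run from 5002 to 6285, with both B libraries also below both A libraries.

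Of 25 measured lysosomal genes, 11 were higher and 0 lower over all genes, and 16 higher and 0 lower adjusted over the list alone, with a median log2 fold change of 0.58 in the authors' deposited table. Cd63, a membrane protein of late endosomes, rose by 1.27 on the log2 scale (adjusted p 1.85e-08), the protease Ctsa by 0.99 (1.17e-05), Gpnmb, a glycoprotein of lysosome-related organelles, by 2.35 (0.000169) and the acid ceramidase Asah1 by 0.83 (0.000431), all in the authors' deposited table. The random-list adjusted p was 0.00116, and the adjusted p = 0.57 with an estimated correlation. Both B libraries were above both A libraries for 21 of the 25 members. The same held for 13 of 18 macrophage-lineage markers, a list written after the table was seen and without the called genes Lcp1, Ctss, Mpeg1 and C3ar1, with a median log2 fold change of 1.39 in the authors' deposited table and 3 members called higher and 1 lower. Endoderm markers had both B libraries above both A libraries in 12 of 19 members. Feeder fibroblast markers had 0 of 27 members so separated and differed within groups, with a median log2 ratio of 2.27 for B2 over B1 and 1.07 for A1 over A2.

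Pluripotency lists had medians below 0, while endoderm markers had both B libraries above both A libraries in 12 of 19 members. General pluripotency factors had 0 higher and 3 lower of 11 measured members over all genes and 0 higher and 6 lower adjusted over the list alone (median log2 fold change -0.45, authors' deposited table). These were Utf1, with a mean of 47093 in group A and 23521 in group B (adjusted p 0.000237), L1td1 (-0.65, adjusted p 0.0177) and the RNA-binding protein Lin28a (-0.62, adjusted p 0.034) in the authors' deposited table. Naive markers had 3 of 21 members lower over all genes and 4 adjusted over the list alone, with 0 higher in each count (median -0.19, authors' deposited table). They were Socs3, the feedback inhibitor of LIF signalling (-0.97, adjusted p 2.44e-05), Fgf4 (-1.01, adjusted p 0.000347) and Prdm14 (-0.66, adjusted p 0.0251), per the authors' deposited table. Random-list adjusted p values were 0.00116 for the general and 0.00797 for the naive list, and for each the adjusted p = 0.57 with an estimated correlation. With random lists not matched on expression the naive list missed the threshold (adjusted p 0.108). Of 15 primed and formative markers 3 were lower over all genes and 4 adjusted over the list alone, and 0 were higher. In the authors' deposited table these were Foxd3 (-1.15, adjusted p 3.61e-07), Otx2 (means of 1113 in A and 556 in B, adjusted p 0.000389) and Pou3f1 (604 and 302, adjusted p 0.00482), and the list's random-list adjusted p was 0.0554, or 0.0116 with a mean of at least 50, 0.0344 with B1 alone and 0.0360 with B2 alone, and the adjusted p = 0.57 with an estimated correlation.

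Markers of the 2-cell-like state, a rare and fluctuating state of such cultures, had the lowest list median, -2.26 in the authors' deposited table. Of 15 measured members 0 were higher and 3 lower over all genes, and 0 higher and 7 lower adjusted over the list alone. Duxf3 (-2.31, adjusted p 0.0168), Zscan4b (-2.41, adjusted p 0.0314) and Zscan4e (-2.40, adjusted p 0.0359) fell in the authors' deposited table, and none of the 3 passed in limma on all libraries. Limma called 0 members in either direction with all libraries. Its median log2 fold change of the list was -1.75 without A1, -2.84 without A2, -2.80 without B1 and -1.59 without B2. These genes have near-identical copies, so reads may have been split among them and their values are uncertain. The random-list adjusted p was 0.00116, and the adjusted p = 0.61 with an estimated correlation. The libraries of each group also differed, with median normalized counts of the list of 229 in A1, 139 in A2, 106 in B1 and 41.4 in B2.

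Lists of germ layer markers had medians on both sides of 0. Endoderm markers had the highest list median, 1.62 in the authors' deposited table, with 1 of 19 members higher over all genes and 6 adjusted over the list alone, and 0 lower in each count. The member past the threshold was the transcription factor Foxa1 (log2 fold change 2.95, adjusted p 0.0192, authors' deposited table). The random-list adjusted p was 0.00116, and the adjusted p = 0.61 with an estimated correlation. Median normalized counts of this list were 1197 in A1, 770 in A2, 6499 in B1 and 2472 in B2, so B1 was the higher of the B libraries, whereas feeder fibroblast markers were higher in B2 (5603) than in B1 (1545). Limma called 5 endoderm members higher and 0 lower with all libraries. Its median log2 fold change of the list was 1.66 without A1, 1.37 without A2, 0.96 without B1 and 2.08 without B2. Of 19 primitive streak and mesendoderm markers 3 were higher and 0 lower over all genes, and 3 were higher and 1 lower adjusted over the list alone. Besides T, they were Snai1, a repressor of E-cadherin (1.56, adjusted p 5.43e-12), and the homeobox gene Cdx1 (2.17, adjusted p 0.0209), by the authors' deposited table. The streak list shares T, Cdx1, Cdx2 and Wnt3 with the canonical Wnt target list, so the results of these lists are not separate. The random-list adjusted p of this list was 0.106, and it passed with a mean of at least 50 (median 0.64, adjusted p 0.000725) and with the mean in place of the median (0.66, adjusted p 0.00644), against an adjusted p = 0.57 with an estimated correlation. Of 12 neuroectoderm markers 0 were higher and 3 lower over all genes, and 0 higher and 4 lower adjusted over the list alone (random-list adjusted p 0.0763). This list passed with a mean of at least 50 (median -0.80, adjusted p 0.000725) and with the mean in place of the median (-0.50, adjusted p 0.0377), against an adjusted p = 0.57 with an estimated correlation. Its median was -1.21 with B1 alone (adjusted p 0.000725) and -0.16 with B2 alone (adjusted p 0.279). Gbx2 (-1.31, adjusted p 7.26e-09), Sox1 (-1.27, adjusted p 0.00906) and the adhesion molecule Ncam1 (-1.19, adjusted p 0.00932) fell in the authors' deposited table. Trophectoderm markers had 1 of 14 members higher over all genes and 2 adjusted over the list alone, with 0 lower, and the member was the keratin Krt18 (1.72, adjusted p 1.08e-13, authors' deposited table). That list's random-list adjusted p was 0.0296, and the adjusted p = 0.57 with an estimated correlation. It was 0.101 with B1 alone and 0.0939 with B2 alone.

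**Figure D2:**
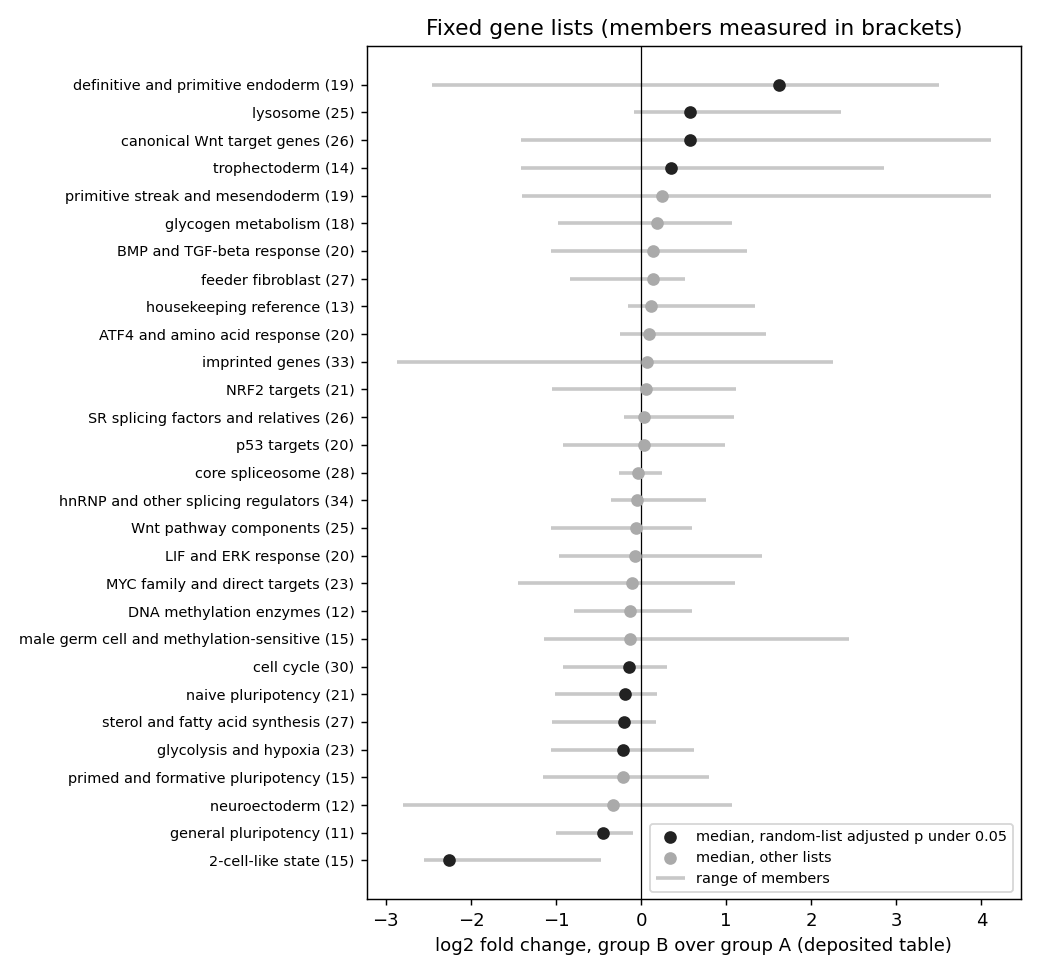
Median log2 fold change of group B over group A (horizontal axis, authors' deposited table) of the 29 gene lists tested, with the number of measured members in brackets and bars from the lowest to the highest member. The 10 black points are lists with a random-list adjusted p under 0.05, and medians run from -2.26 for the 2-cell-like state to 1.62 for endoderm.

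Genes of splicing, the process named in the series title, had no member past the threshold of the authors' test in either direction. This held for 26 SR splicing factors, 34 hnRNP and other splicing regulators and 28 core spliceosome proteins, over all genes and adjusted over the list alone. Log2 fold changes in the authors' deposited table were -0.07 for Srsf3, 0.02 for Srrm2, -0.13 for Hnrnpa2b1, 0.05 for Hnrnpf, -0.25 for Prpf8 and -0.20 for Snrnp200, with adjusted p values of 0.884 for Prpf8 and 1 for the others. In limma without B2, 2 of the 34 hnRNP and other regulators passed, Esrp2 (log2 fold change 1.07, adjusted p = 0.0361) and Rbm25 (0.43, adjusted p = 0.0469), named after their values were seen, and no splicing gene passed with all libraries or without A1, A2 or B1. Random-list adjusted p values of the lists were 0.414, 0.253 and 0.582. The SR list passed with B1 alone (median 0.15, adjusted p 0.0213) and not with B2 alone (-0.07, adjusted p 0.471), and the adjusted p = 0.92 with an estimated correlation. Enzymes of glycogen metabolism likewise had 0 of 18 members past the threshold by both counts (random-list adjusted p 0.128), with log2 fold changes of 0.20 for Gaa and 0.05 for Pgm1 in the authors' deposited table.

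Among imprinted genes 3 of 33 were higher and 3 lower over all genes, and 5 higher and 5 lower adjusted over the list alone. In the authors' deposited table the cell-cycle inhibitor Cdkn1c fell by 2.87 on the log2 scale (adjusted p 1.35e-20) and its neighbour Phlda2 by 1.75 (4.84e-16). The zinc finger gene Plagl1 rose by 1.34 (adjusted p 1.55e-10) and Airn, a non-coding RNA antisense to Igf2r, by 2.26 (7.85e-05), by the authors' deposited table. The Airn value is uncertain because the strand setting of the counting is not given. The list's random-list adjusted p was 0.322, and its median of 0.07 and mean of -0.01 differed in sign. It passed with B2 alone (median 0.36, adjusted p 0.000725) and not with B1 alone (-0.07, adjusted p 0.402), and the adjusted p = 0.92 with an estimated correlation.

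Most proliferation genes did not pass, as was so for genes at large. Of 20349 genes with a mean of at least 10 and a chromosome position, 1039 passed. Of 30 cell cycle genes 2 were lower and 0 higher by both counts, the cyclins Ccnd3 (-0.92, adjusted p 4.23e-05) and Ccne1 (-0.71, adjusted p 0.00539) in the authors' deposited table. The list passed the random-list test (adjusted p 0.00967; adjusted p = 0.57 with an estimated correlation) and missed it with unmatched random lists (adjusted p 0.110). In the MYC list, 1 of 23 members was higher and 2 lower by both counts, and its random-list adjusted p was 0.0677, or 0.0464 with the mean in place of the median, against an adjusted p = 0.75 with an estimated correlation. With B2 alone its median was -0.22 (adjusted p 0.00725) and with B1 alone -0.0077 (adjusted p 0.544). Mycl rose by 1.10 on the log2 scale (adjusted p 4.40e-06), while Mycn fell by 1.44 (4.63e-05) and Myc by 0.71 (0.00779), as given in the authors' deposited table. Among 20 p53 targets the cell-cycle inhibitor Cdkn1a rose (0.99, adjusted p 1.73e-05) and the apoptosis gene Bbc3 fell (-0.92, adjusted p 0.0102) in the authors' deposited table, with 2 higher and 1 lower adjusted over the list alone (random-list adjusted p 0.554). That list passed with B2 alone (median 0.16, adjusted p 0.0147) and not with B1 alone (-0.03, adjusted p 0.402), and the adjusted p = 0.92 with an estimated correlation.

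Few members of the metabolic lists passed. Sterol and fatty acid synthesis had 1 of 27 members lower over all genes and 2 adjusted over the list alone, with 0 higher, and the member was the mevalonate pathway enzyme Pmvk (-0.76, adjusted p 0.00247, authors' deposited table). The list's random-list adjusted p was 0.00483, and the adjusted p = 0.68 with an estimated correlation. It was 0.0507 with unmatched random lists and 0.101 with B1 alone. Glycolysis and hypoxia genes had 0 of 23 past the threshold over all genes and 1 higher and 1 lower adjusted over the list alone, with log2 fold changes of -0.17 for Pkm and 0.62 for Slc2a3 in the authors' deposited table. The list had a random-list adjusted p of 0.00497, and the adjusted p = 0.77 with an estimated correlation. It was 0.0719 with unmatched random lists and 0.110 with B2 alone. NRF2 targets had 1 of 21 members lower over all genes and 2 adjusted over the list alone, with 0 higher (random-list adjusted p 0.486). That gene was the glutathione transferase Gsta4 (-0.67, adjusted p 0.00894, authors' deposited table). None of 20 genes of the ATF4 and amino acid response passed by either count (random-list adjusted p 0.269), with log2 fold changes of 0.25 for Asns and -0.04 for Slc3a2 in the authors' deposited table.

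Signalling and chromatin lists completed the set. Of 20 LIF and ERK response genes 2 were lower and 0 higher by both counts, Socs3 and Spry4 (-0.69, adjusted p 0.00398, authors' deposited table), with a random-list adjusted p of 0.301. The list passed in opposite directions with B1 alone (median -0.26, adjusted p 0.00232) and with B2 alone (0.15, adjusted p 0.0460), and the adjusted p = 0.92 with an estimated correlation. BMP and TGF-beta response genes had 0 of 20 past the threshold by both counts (random-list adjusted p 0.161), with 0.16 for Smad7 and 0.15 for Bmp4 on the log2 scale in the authors' deposited table. They passed as a list with B2 alone (median 0.33, adjusted p 0.00406) and not with B1 alone (-0.07, adjusted p 0.445), and the adjusted p = 0.92 with an estimated correlation. DNA methylation enzymes had 0 of 12 past it over all genes and 4 lower adjusted over the list alone (random-list adjusted p 0.128), with -0.05 for Uhrf1 and -0.52 for Dnmt3l in the authors' deposited table. Male germ cell genes had 1 of 15 higher and 3 lower by both counts (random-list adjusted p 0.260), with a median of -0.13 and a mean of 0.01. By the authors' deposited table, Sycp3 (-1.02, adjusted p 5.78e-05), Mael (-0.90, adjusted p 0.000374) and Tuba3a (-1.14, adjusted p 0.0405) fell and Brdt rose (1.13, adjusted p 0.00523). Of 13 housekeeping references 1 passed by both counts, B2m, a subunit of MHC class I (1.34, adjusted p 0.000275, authors' deposited table), with a list median of 0.12 and a random-list adjusted p of 0.128.

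Beyond the lists, Foxf2 (3.90, adjusted p 0.0186), the serotonin receptor Htr5a (3.83, adjusted p 8.89e-24), Cpxm2 (3.69, adjusted p 2.08e-49), Mogat2 (3.67, adjusted p 0.00743) and Foxq1 (3.63, adjusted p 0.0339) had the largest increases after T, beside Sp5, in the authors' deposited table. Fam181b, Tlx2, Krt23, Dmkn and the actin-bundling protein Lcp1 followed, with log2 fold changes from 3.07 to 3.31 in the authors' deposited table. The largest decreases in the authors' deposited table were those of the homeobox gene Nkx6-3 (-4.12, adjusted p 7.28e-56), Atp1a4 (-3.70, adjusted p 2.38e-08), Trim52 (-3.45, adjusted p 5.17e-19), the opioid precursor Pdyn (-3.10, adjusted p 5.72e-05) and the lysine-degrading enzyme Aass (-2.99, adjusted p 1.41e-34). Pkhd1, Spink1, Pak6, the Notch ligand Dll1 and the T-cell receptor segments Trav5-2 and Trav5n-2 lay between -2.96 and -2.54 on the log2 scale in the authors' deposited table. The Trav5 segments have close copies and their values are uncertain. Of these genes, only Foxf2 missed the limma threshold (4.07, SE 0.69, adjusted p = 0.0514). Of all 88 named genes 48 passed in both tests, others such as Gsk3b passed in neither, and 21 lost their call in limma. Besides Foxf2 and the 3 genes of the 2-cell-like state they were Ctsa, Sycp3, Airn, Prdm14, L1td1, Bbc3, Fgf4, Wnt7b, Otx2, B2m, Spry4, Brdt, Lin28a, Pou3f1, Ncam1, Sox1 and Tuba3a, with limma adjusted p values from 0.0503 for Ctsa to 0.153 for Duxf3.

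**Figure D3:**
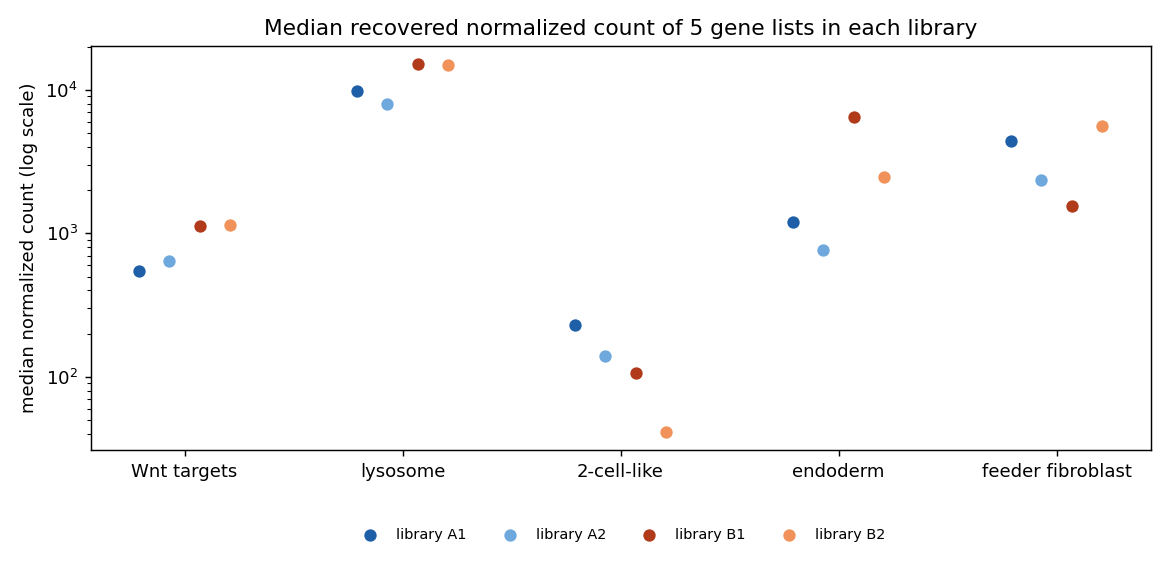
Median recovered normalized count (vertical log axis) of the members of 5 gene lists in libraries A1 and A2 (blue) and B1 and B2 (orange), 1 point per library. Wnt target medians are 551 and 647 in the A libraries and 1126 and 1149 in the B libraries, whereas the feeder fibroblast median is 1545 in B1 and 5603 in B2 and spans both A libraries.

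Feeder fibroblast markers, which show RNA of the supporting cells, had 0 of 27 members past the threshold by both counts. Their median log2 fold change was 0.15 in the authors' deposited table (random-list adjusted p 0.121), while camera placed the list in the other direction (adjusted p 0.466 with the preset correlation). The median was -1.48 with B1 alone and 0.78 with B2 alone, each with an adjusted p of 0.000725, and the adjusted p = 0.92 with an estimated correlation. Col1a2 had recovered normalized counts of 37638, 17900, 9468 and 56892 and Col1a1 of 31482, 17177, 8757 and 55013 in A1, A2, B1 and B2. Library B2 also held the largest share of counts in ribosomal RNA genes, 1.08% against 0.216% to 0.352% in the other libraries. With camera and the preset correlation 13 of the 29 lists passed, and with an estimated correlation 0 did. For the Wnt list the estimated correlation was -0.03, yet its unadjusted camera p was 1.15e-06 preset and 0.0322 estimated. The power of the estimated setting with so few libraries was not measured. Its 0 lists do not show that a list is unchanged, and they give no list support. Estimated-correlation adjusted p values ran from 0.568 to 0.921, and unadjusted ones from 0.0322 upward, so camera left the Wnt list as the single list under 0.05 before adjustment. No gene of the X and Y chromosome list had a count.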

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

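The alternatives on recovered counts, the leave-one-out fits, the protein-coding count and the values of single libraries were chosen after seeing the data, and the other alternatives before. The count of 1047 genes became 674 at an adjusted p of 0.01 and 602 with an absolute log2 fold change of at least 1, by construction. It lay between 947 and 1366 with a mean of at least 50, an adjusted p of 0.10, adjustment over means of at least 10, and protein-coding genes alone. Limma on the recovered counts called 411 genes, 391 and 495 with pseudocounts of 0.1 and 5, 439 with a mean of at least 50, 412 with any mean, and 448 with scaling by total count, and the cause of the lower counts was not tested. Leaving out 1 library gave 0 to 1111 genes in limma, 0 without A1 or A2 and 997 and 1111 without B1 or B2. Then the lone library is assumed to vary like the remaining pair, and the spread comes from 1 pair, which without A1 or A2 is the more variable B pair. The Gsk3a value was -2.26 relative to housekeeping genes and -2.15 with centring, where the authors' p is kept and no call can change, and -2.15 and past the threshold in limma on all libraries. Leaving out 1 library gave -2.32 to -1.98, past the threshold without B1 or B2 and not without A1 or A2.

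The 10 lists became 6 with random lists not matched on expression, where the naive, cell cycle, sterol and glycolysis lists lost their call, and 0 in camera with an estimated correlation, and 10 to 15 under the other settings. The cause was not tested, and the power of the estimated setting with so few libraries was not measured. Leaving out centring, which shifts list and random lists alike and cannot change a call, 206 single-list values kept their direction and side of the threshold or were past it in neither, 16 gained and 8 lost the call, and 2 reversed, feeder fibroblast at -1.48 with B1 alone and LIF and ERK response at 0.15 with B2 alone. In 12 of the 206 the sign changed near 0. In limma 67 named genes kept their side of the threshold, 48 of them past it in both tests, and 21 lost their call. Among the 67, 2 past it in neither test changed sign. They were Col1a1 (0.39 in the authors' deposited table, -0.08 in limma) and Col1a2 (0.26 and -0.16). No paired analysis was possible because neither the group means nor the recovered libraries carry the replicate numbers of the labels. The planned DESeq2 alternative was not run, and the recovered counts were tested with limma alone. The main count already has no filter beyond a mean above 0. Depth limits the genes near the minimum mean of 10, whose counting error is large.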

Other observations

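Tests on the genotype of the groups, the missing chromosomes and the feeder markers were chosen only after the result was seen; those on chromosome dosage, macrophage markers, neighbouring genes and other splits were written before their result was seen. Genes named in this part were chosen after their values were seen. The neighbouring genes Bhmt, Bhmt2 and Dmgdh on chromosome 13, which encode enzymes of betaine and dimethylglycine metabolism, were all higher in group B, with log2 fold changes of 2.43, 2.18 and 2.43 and adjusted p values of 1.70e-19, 5.64e-17 and 2.10e-29 in the authors' deposited table. Fabp3, a fatty acid carrier, rose by 2.24 and its processed copy Fabp3-ps1 by 2.27 in the authors' deposited table, and both values are uncertain because the copies can share reads.

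Endoderm factors that did not pass the authors' threshold still stood far apart between the groups in the recovered counts. Normalized counts of Gata6 were 744 in A1, 535 in A2, 8215 in B1 and 3503 in B2, and those of Sox17 271, 140, 3231 and 1427. In the authors' deposited table their log2 fold changes were 3.20 (adjusted p 0.117) and 3.50 (adjusted p 0.0652). With limma the adjusted p was 0.034 for Gata6 and 0.0365 for Sox17. Other endoderm members went the other way without passing, such as Ttr (-2.46, adjusted p 0.429) and Cubn (-0.60, adjusted p 1) in the authors' deposited table.

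The genotype of group B is a hypothesis and entered no comparison. If group B were the double knockout, canonical Wnt targets would be higher there, and 8 were called higher in B and 0 lower. If group A were the double knockout, Gsk3a would be higher in B, and its log2 fold change was -2.14, which argues against it. The Wnt target counts argue against it too, and both results point to group B as the double knockout. They come from the same comparison and no label names the groups, so the report keeps the letters A and B.

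No gene on chromosomes X, Y or M had a count, 0 of 4208, against 71.8% of 41797 genes on numbered chromosomes. A candidate explanation is that only numbered chromosomes were counted or kept, and the 86 genes on unplaced scaffolds, which could have had counts, had none, so that X, Y, M and scaffolds together gave 0. On chromosome 1, 4 unprocessed pseudogenes were among the 7 genes with the highest means. Their transcripts matched mitochondrial ones at 100% (Gm10925 to mt-Atp6, Gm28437 to mt-Co3, Gm28661 to mt-Co2) and 99.8% (Gm29216 to mt-Co1). Whether their reads came from mitochondrial transcripts or from the nuclear copies was not tested, and whether genes were dropped before or after alignment stays open.

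Feeder fibroblast markers were 4.84-fold higher in B2 than in B1 by their median and 2.10-fold higher in A1 than in A2. Whether feeder RNA differs between the groups or adds to the called genes stays open. None of 27 members had both B libraries on the same side of both A libraries, which only restates that their median was lowest in B1 and highest in B2. The called genes' median log2 ratio of B2 over B1, -0.0794 in genes called higher in B and -0.00040 in genes called lower, decides nothing, because a call needs B libraries that resemble each other. B2 further had 1.08% of its counts in ribosomal RNA genes, against 0.216% in B1, 0.302% in A1 and 0.352% in A2. A gained or lost chromosome in 1 group would shift a whole chromosome, and the largest absolute value of 19 chromosome medians was 0.12 on the log2 scale, on chromosome 12.

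Macrophage-lineage genes stood among those higher in B, such as Lcp1, Ctss, Mpeg1 and C3ar1, with log2 fold changes of 3.07, 2.86, 2.40 and 2.39 in the authors' deposited table. Cells of this lineage in the cultures of group B may be a source. Of 18 measured markers 3 were called higher (Spi1, Ptprc and Lyz2) and 1 lower (Mrc1), and 13 had both B libraries above both A libraries, with a median log2 fold change of 1.39. The list leaves out Lcp1, Ctss, Mpeg1 and C3ar1, which are all called higher, and with these 4 the count is 7 of 22. None of the 19 listed markers is in another list used here. The 3 called fell within the bound written in advance as evidence against this source. The 7 of 22 lie outside it by construction, because the 4 added genes were chosen for being called higher. That bound was set aside after the value was seen, because only 28.8% of 539 other genes of like mean and absolute fold were called. Each of the 539 had both B libraries on the same side of both A libraries, on either side, which was not required of the markers. Abundant markers such as Laptm5 (24895 in group A and 20943 in group B) and Cd68 (2603 and 2044) in the authors' deposited table were not higher in B. The median of the marker means was 95.1, so markers this abundant need not follow a small number of macrophage cells. The question stays open.

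Called genes lay beside each other more often than in random placements not matched on mean expression. The nearest neighbour was called in the same direction for 9.72% of 1039 called genes with a mean of at least 10, against 0.770 to 4.52% in 1000 random placements. For neighbours that differ in the first 3 letters of the symbol, among protein-coding genes, the share was 6.94% against 1.16 to 5.42%. Neighbouring genes may change together in part, though genes of 1 family can share reads and regulation. Of the 1047 called genes 1000 had a mean of at least 50, against 16553 of 20465 genes with a mean of at least 10. Neighbours of like mean could therefore raise the share. Limma on the recovered counts called 411 genes for the real split of the 4 libraries and at most 0 for the other 2 splits, which had 301 and 428 genes at an unadjusted p under 0.05. The real split was the only 1 of 3 to call as many, and 3 splits are too few for a share under 0.05. Both other splits place 1 A and 1 B library in each group, so the difference between A and B widens their spread. Their 0 calls are therefore no baseline for the 411.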
